A study of Sus scrofa with 48 samples.

How the data were processed

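RNA of liver and fat from 24 Yorkshire gilts was hybridised to 48 Affymetrix porcine arrays. Per the labels, RNA was prepared with a column kit and DNase, and labelled with biotin by the one-cycle method. The submitters' processing notes name the affy package and the MAS5 method, with no versions, and say nothing on filters. The deposited table holds 1 signal intensity per probe set and array on a linear scale, with no zeros. The deposited intensities had been scaled by the authors to a common level: the mean without the lowest and highest 2% of values is 500 on every array. Log2 of these values was taken with nothing added. No array was a copy of another.

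Of 24123 probe sets, 124 spiked-in and other control probe sets were left out and 23999 were tested, with no filter on dim signal. The annotation supplied gave 1 gene symbol for 10069 probe sets, several for 198 and none for 13732. Of the probe sets with 1 symbol 9961 were matched by gene ID to the RefSeq gene table of the pig, and no symbol changed. For names and gene lists each of 6765 genes was represented by its brightest probe set over all arrays, and 2261 genes had more than 1. Symbols are used as identifiers, and positions are not printed.

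Genotype, feeding state and replicate number were taken from the labels. In each tissue a linear model was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), with the 4 groups of genotype and feeding and the replicate number as a block of 6 levels, since the labels describe a block design. Contrasts were fasted minus fed, N298 minus D298, their interaction, and both effects within each level of the other. All tests were 2-sided, and p values were adjusted by Benjamini and Hochberg over the probe sets tested. A probe set was called at an adjusted p under 0.05, and an error given as SE is that of the log2 fold change in this model. The difference of the fasting responses of liver and fat was tested on all 48 arrays with the gilt as a random block (within-gilt correlation 0.084). Liver and fat arrays were joined to gilts by genotype, feeding state and number. This was checked on residual expression, in which 21 of 24 liver arrays correlated best with the fat array of their own number, with r from 0.046 to 0.321.

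The 35 gene lists were fixed before the data were examined, as were all choices here except those the closing section names as later ones. They cover fatty acid, cholesterol and triglyceride synthesis, fatty acid oxidation, PPARA-responsive genes, gluconeogenesis, glycolysis, amino acid catabolism, lipid droplets, adipokines, the growth hormone axis, insulin and FOXO signalling, the clock, protein folding, heat shock, the tricarboxylic acid cycle, oxidative phosphorylation, ribosomes, the proteasome, autophagy, cell cycle, matrix, acute phase, bile acids, xenobiotics, the melanocortin system, interferon response and the markers of 8 other cell types. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which tests whether the genes of a list move on balance in 1 direction. Each list is described by how many members were called over all probe sets and when adjusted over the list alone.

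Genes are named by a rule. For fasting in each tissue it takes the 10 largest rises and 10 largest falls among genes with 1 symbol that passed, had the same sign in both genotypes and a mean signal in the upper part of the range (above the median probe set of the tissue). For the tissue difference it takes 5 in each direction, and for genotype and interaction the 5 with the smallest p where fewer passed. For each list it takes up to 4 members in the main direction and 2 in the other by p, and a few genes fixed by name. Genes so named in 1 tissue are given in the other where both are compared.

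Alternatives included no block or a random block, quantile normalization, median-centring, only the brighter probe sets, 32 added before log2, eBayes without trend, array weights and leaving out each replicate number. After seeing the data, fits without certain arrays, with marker list means or an RNA quality ratio as covariates, and a genotype contrast over both tissues were added. Groups of 12 were compared in list means and control ratios by 2-sided permutation tests (100000 resamples, SciPy 1.17.1), adjusted over the 17 measures of each family. The models were tested on simulated data: in normal noise with the mean and residual SD of each probe set, 50 probe sets per fold and comparison were changed by 1.25, 1.5, 2 or 4-fold, and the share called was counted. Tables and figures used pandas 2.3.3 and Matplotlib 3.10.9 in Python 3.11.15.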

Results

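Gene expression was measured on 48 arrays, 1 for the liver and 1 for the fat of each of 24 Yorkshire gilts. The gilts were 6 months old and came from a line selected for low residual feed intake, that is, for eating less than their growth and body weight predict. Genotype and feeding were crossed: gilts carried either the wildtype D298 or the N298 form of MC4R, the melanocortin 4 receptor that acts in the brain on appetite and energy use, and were either fed freely or fasted for 3 days. Each of the 8 groups of tissue, genotype and feeding state held 6 arrays. The deposited signals were scaled alike, so that the median signal of an array lay between 122 and 149 in liver and between 159 and 192 in fat. An array's median correlation with the others of its group was 0.930 to 0.970 in liver and 0.911 to 0.964 in fat. The number of arrays limits the precision of all values.

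The first question was how the liver responds to 3 days without feed. In fasted liver 12 of 13 cholesterol genes and 8 of 14 fatty acid synthesis genes were lower, and 12 of 24 genes of fatty acid oxidation and ketogenesis were higher. As lists only the cholesterol genes held with an estimated correlation between genes (adjusted p = 0.000532, against 0.176 for each of the others). Pyruvate carboxylase (PC), which makes oxaloacetate from pyruvate, rose 3.58-fold (log2 1.84 ± 0.090 SE, 12 fasted against 12 fed gilts, adjusted p = 1.18e-11). LDHB, a subunit of lactate dehydrogenase, rose 3.45-fold (log2 1.79 ± 0.10 SE). The steepest falls by the naming rule were in fatty acid synthase (FASN), by 3.22 ± 0.18 (SE) on the log2 scale to 0.108 of the fed level, and in the sterol pathway thiolase ACAT2, which fell by 3.08 ± 0.13 (SE).

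Of 23999 probe sets, 1073 passed the threshold of adjusted p under 0.05 in limma, 545 higher and 528 lower in fasted liver, and 65 of the rises and 116 of the falls were at least 2-fold. Of the 6765 genes represented by 1 probe set each, 487 passed in liver, 277 higher and 210 lower. The 10 largest rises by the naming rule also held the cytochrome P450 CYP2C36 (log2 3.27 ± 0.59 SE), the imprinted gene neuronatin (NNAT, 3.08 ± 0.33), the apolipoprotein APOA4 (2.80 ± 0.39) and the phosphomannomutase PMM1 (2.21 ± 0.29). The others were MDFIC (1.69), the beta-defensin DEFB1 (1.63), LOC100624460 (1.61) and the short-chain dehydrogenase DHRS4 (1.60). A further CYP2C36 probe set gave -1.02 and a further DEFB1 probe set -0.03, so these 2 rises rest on 1 probe set each. Among the falls were squalene epoxidase (SQLE, -2.99 ± 0.19), HMG-CoA synthase (HMGCS1, -2.93 ± 0.15), farnesyl diphosphate synthase (FDPS, -2.69), lanosterol demethylase (CYP51, -2.60) and the sterol reductase TM7SF2 (-2.29). Acetyl-CoA synthetase (ACSS2, -2.27), the inositol oxygenase MIOX (-2.07) and the secreted protein TSKU (-1.88) completed the 10 falls.

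**Figure D1:**
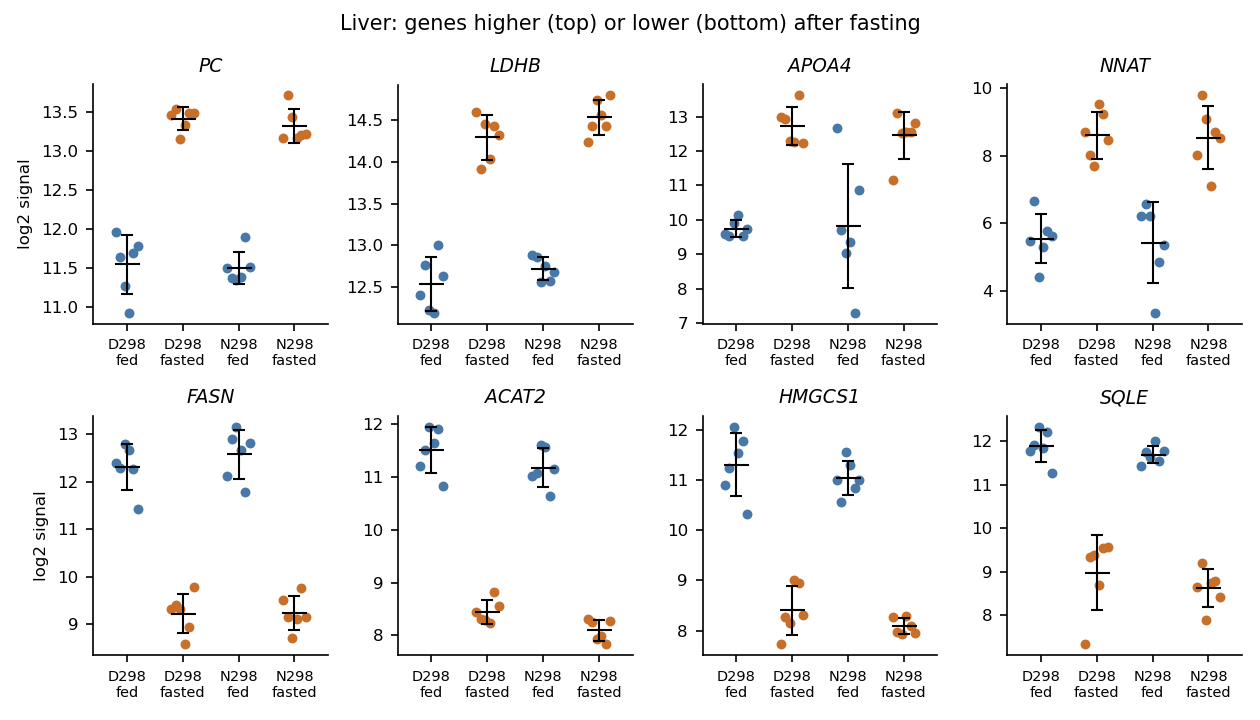
Log2 signal of 8 genes in liver, 1 point per gilt, with the mean and SD of each group of 6. PC, LDHB, APOA4 and NNAT (top) were higher and FASN, ACAT2, HMGCS1 and SQLE (bottom) lower in fasted gilts; mean log2 PC was 11.55 in fed and 13.42 in fasted D298 gilts, and 11.51 and 13.32 in N298 gilts.

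Cholesterol synthesis and uptake was the list that changed most evenly in liver: 12 of 13 measured members fell, and 12 fell adjusted over the list alone. SC5D, a desaturase of the late pathway, fell by 1.81. The list's median was -1.81, and its camera call held with a preset correlation (adjusted p = 4.97e-34) and with an estimated one (adjusted p = 0.000532). It was the only list of 35 to hold with an estimated correlation in this comparison. In fatty acid synthesis 8 of 14 members fell and 1 rose (10 and 3 adjusted over the list alone), with falls in malic enzyme (ME1, -1.33) and transketolase (TKT, -0.77). The mitochondrial citrate carrier SLC25A1 rose (0.44), and ELOVL6, an elongase, gave 0.71 and passed only without replicate number 5. For this list the adjusted p was 1.82e-07 with the preset correlation and 0.176 with an estimated one.

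Fatty acid oxidation and ketogenesis moved the other way in liver, with 12 of 24 members higher, 3 lower and 9 not past the threshold (14 higher and 5 lower adjusted over the list alone). ACADVL, the very long chain acyl-CoA dehydrogenase, rose by 1.58 ± 0.096 (SE), HADHA of the trifunctional protein by 1.22, ECH1 by 1.13 and the electron transfer dehydrogenase ETFDH by 0.77. DECR1 (-0.58) and ECI1 (-0.33), which act on unsaturated fatty acids, fell. The camera call (adjusted p = 2.74e-06) was lost with an estimated correlation (adjusted p = 0.176). In the lipid droplet list 4 of 11 members rose and none fell (5 and 0 adjusted over the list alone): the droplet coat proteins PLIN2 (0.98) and PLIN3 (0.96), the lipase activator ABHD5 (0.72) and the fatty acid binding protein FABP4 (1.37). Its adjusted p was 0.00747 with the preset and 0.176 with an estimated correlation. Of 11 triglyceride synthesis genes 3 fell, LPIN1 (-1.32), LPIN2 (-0.85) and DGAT1 (-0.49), with 3 higher and 4 lower adjusted over the list alone.

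Some gluconeogenesis genes rose in liver. PC, the mitochondrial PEP carboxykinase PCK2 (0.47), fructose bisphosphatase (FBP1, 0.34) and the glucose 6-phosphate transporter SLC37A4 (0.57) rose, 4 of 12, and none fell (5 and 4 adjusted over the list alone). The cytosolic PEP carboxykinase PCK1 gave -0.038 ± 0.11 (SE) in liver and did not pass. Of 20 genes on the tricarboxylic acid cycle list 5 rose and none fell (7 and 2 adjusted over the list alone). Among the rises were SUCLG1 (0.29), FH (0.31), SDHD (0.29) and IDH1 (0.87), which encodes a cytosolic form of isocitrate dehydrogenase. The adjusted p of that list was 0.0200 with the preset and 0.371 with an estimated correlation. No member of the 31 oxidative phosphorylation genes passed in liver. In the growth hormone axis the IGF carrier subunit IGFALS (-0.84) and IGF2 (-0.33) fell and IGFBP2 (0.62) rose among 15 genes (2 lower and 1 higher adjusted over the list alone), with adjusted p = 0.293 with an estimated correlation. Of the clock genes BHLHE40 (-0.96) and PER1 (-0.56) fell, 2 of 7, with 1 higher and 4 lower adjusted over the list alone.

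Nitrogen and glucose metabolism lists held further single changes in liver. In the urea cycle and amino acid list 3 of 14 rose, CTH (0.43), ARG1 (0.41) and BCKDHB (0.35), and none fell (5 and 1 adjusted over the list alone, adjusted p = 0.381 with an estimated correlation). In glycolysis PFKL (0.85), GPI (0.54) and LDHA (0.46) rose and ENO1 (-0.33) and PGK1 (-0.33) fell (3 and 3 adjusted over the list alone), with a list median of -0.035 and a mean of 0.017. Of 8 PPARA-responsive genes PLIN2 and VNN1 (0.97) rose and FABP1 (-0.34) fell (2 and 1 adjusted over the list alone), with a median of -0.11 and a mean of 0.080. Of 23 xenobiotic genes 5 fell, among them CYP2B22 (-1.81) and EPHX1 (-0.55), and 2 rose, SULT2A1 (0.56) and ABCB1 (0.47) (8 and 2 adjusted over the list alone, adjusted p = 0.371 with an estimated correlation). CTSH (-0.63), MAP1LC3A (-0.56) and GABARAPL1 (-0.28) fell, 3 of 19 autophagy genes (3 lower and 1 higher adjusted over the list alone), and the bile acid carrier SLC10A1 (-0.68) fell, 1 of 7 (3 lower and 1 higher adjusted over the list alone).

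Lists of cell division, matrix and protein synthesis moved by few called members in liver. In the cell cycle list MCM2 fell (-0.84), 1 of 18, with 9 lower adjusted over the list alone, a median of -0.57 and adjusted p = 0.371 with an estimated correlation. POSTN (-0.54) and SPARC (-0.39) fell, 2 of 21 matrix genes, with 5 adjusted over the list alone and adjusted p = 0.176 with an estimated correlation. ITIH3 (-0.26) fell, 1 of 17 acute phase genes, with 2 adjusted over the list alone and adjusted p = 0.371 with an estimated correlation. RPS12 rose (0.34), 1 of 50 ribosomal protein genes, with 3 adjusted over the list alone, a median of 0.12 and adjusted p = 0.381 with an estimated correlation. PSMC2 rose (0.21), 1 of 28 proteasome genes, with 0 adjusted over the list alone and adjusted p = 0.610 with an estimated correlation. No member of the protein folding list (17 genes, median 0.21, adjusted p = 0.641 with an estimated correlation), of the heat shock list (14, with 1 higher adjusted over the list alone) or of the insulin and FOXO list (12, with 2 lower) passed. Of the cell type lists, FABP4 rose and NAMPT (-0.55) fell among 14 adipocyte markers, NEB (1.32) rose among 19 muscle markers and KRT10 (0.48) among 6 keratinocyte markers, with the same counts adjusted over the list alone. No member passed among 14 hepatocyte (median -0.076, adjusted p = 0.610 with an estimated correlation), 13 macrophage, 11 lymphocyte, 3 erythroid, 13 endothelial and 8 fibroblast markers or 13 interferon response genes. Adjusted over the list alone, 1 macrophage and 2 erythroid markers fell and 1 erythroid marker rose.

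The liver count depended on replicate number 3, without whose 4 arrays 667 probe sets passed, and ABCB1, ABHD5, ARG1, CPT1A, CTH, DEFB1, FABP1, FABP4, FH, GABARAPL1, IGF2, IGFALS, IGFBP2, ITIH3, KRT10, MCM2, NAMPT, PCK2, PER1, PSMC2, SDHD, SLC25A1, SPARC, SUCLG1, TSKU and VNN1 lost their calls in 1 or more of the fits without certain arrays. After quantile normalization or median-centring ARG1, FABP1, GABARAPL1, IGFALS, ITIH3, MCM2, PGK1 and SPARC lost their calls. FABP4 moved to 0.87 with 32 added before log2. The balance of rises and falls depended on scaling, with 829 higher and 388 lower (68.1% higher, against 50.8%) when each array was centred on its median.

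The same comparison was made in fat. In fasted fat 13 of 14 fatty acid synthesis, all 31 oxidative phosphorylation and 12 of 18 cell cycle genes were lower. As lists none of the 3 held with an estimated correlation between genes (adjusted p = 0.0799, 0.156 and 0.158). Creatine kinase B (CKB) had the steepest fall by the naming rule. It fell by 3.44 ± 0.22 (SE, 12 against 12 gilts) on the log2 scale to 0.0922 of the fed level, and FASN fell by 3.38 ± 0.19 (SE) to 0.096 of it. SLC25A1, which exports the citrate used for fat synthesis from mitochondria, fell by 2.89 ± 0.13 (SE, adjusted p = 1.39e-11). The sulfotransferase SULT1A3 rose 3.15-fold (log2 1.66 ± 0.10 SE, adjusted p = 8.50e-10) and the cytochrome P450 CYP2B22 3.73-fold (log2 1.90 ± 0.26 SE).

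In fat 6048 of 23999 probe sets passed, 3633 higher and 2415 lower after fasting, of which 233 rises and 408 falls were at least 2-fold. Of the 6765 genes represented by 1 probe set each, 2317 passed, 1038 higher and 1279 lower. A list with a like share of called members therefore does not stand out in fat. The remaining large rises by the naming rule were the transcription factor KLF11 (1.67), the glycerol channel AQP3 (1.55), the steroid dehydrogenase HSD3B1 (1.54), the peptidase DPP4 (2.83-fold), PCK1 (1.45), ITIH1 (1.44), plasmolipin (PLLP, 1.37) and GPIHBP1 (1.36), which holds lipoprotein lipase on capillaries. The remaining falls were PGLYRP2 (-3.19), a peptidoglycan amidase, ACSS2 (-2.61), the cholesterol transporter STAR (-2.59), PSPH of serine synthesis (-2.55), acetyl-CoA carboxylase (ACACA, -2.47), stearoyl-CoA desaturase (SCD, -2.30) and the fructose transporter SLC2A5 (-2.25). A further probe set gave -0.07 for ACACA and 0.13 for ITIH1.

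**Figure D2:**
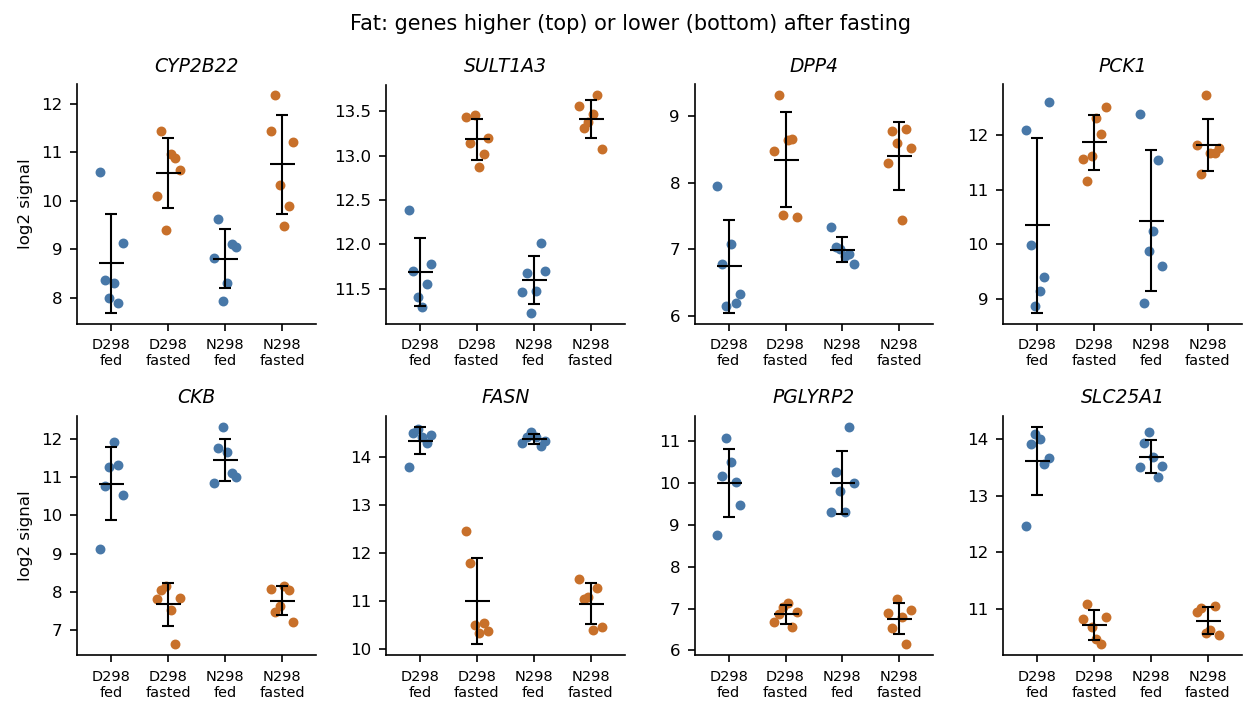
Log2 signal of 8 genes in fat, 1 point per gilt, with the mean and SD of each group of 6. CYP2B22, SULT1A3, DPP4 and PCK1 (top) were higher and CKB, FASN, PGLYRP2 and SLC25A1 (bottom) lower in fasted gilts; 1 fed D298 gilt, replicate number 1, lies toward the fasted gilts in FASN and SLC25A1.

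Fat synthesis genes fell together in fat: 13 of 14 members of the fatty acid synthesis list were lower after fasting, and 13 adjusted over the list alone, with a median of -1.90. Besides FASN, SLC25A1 and ACSS2 these included PGD of the pentose phosphate pathway (-1.56). The camera call (adjusted p = 1.81e-11) was lost with an estimated correlation (adjusted p = 0.0799). Cholesterol genes were lower for 10 of 13 members (11 adjusted over the list alone), such as FDPS (-2.05), ACAT2 (-1.90), SC5D (-1.75) and INSIG1 (-1.05), and that list's adjusted p was 9.48e-07 with the preset and 0.199 with an estimated correlation. Of 11 triglyceride synthesis genes 7 fell (7 adjusted over the list alone), among them DGAT2 (-1.83), AGPAT1 (-1.28), lipoprotein lipase (LPL, -1.03) and DGAT1 (-0.64), with adjusted p = 0.156 with an estimated correlation. In the lipid droplet list HILPDA rose (0.64), 1 of 11, while hormone-sensitive lipase (LIPE) gave 0.16 and passed only after quantile normalization, at 0.35.

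Oxidative phosphorylation genes and most tricarboxylic acid cycle genes were lower in fasted fat. All 31 measured oxidative phosphorylation genes fell, and 31 adjusted over the list alone, with a median of -0.79. Examples were ATP5B (-1.09 ± 0.076 SE), NDUFS3 (-1.18), NDUFB8 (-0.83) and COX5B (-0.92). Of 20 genes on the tricarboxylic acid cycle list 18 fell and 1 rose (18 and 1 adjusted over the list alone), with SDHC at -1.31, MDH2 at -1.27, SDHD at -0.91, MDH1 at -0.81 and ACO1, the rise, at 0.23. MDH1 and ACO1 encode cytosolic forms of these enzymes. With an estimated correlation the adjusted p was 0.156 for both lists, against 1.58e-22 and 3.45e-10 with the preset one. Fatty acid oxidation had 13 falls and 4 rises among 24 genes (13 and 4 adjusted over the list alone). ECI1 (-1.38), ACSL1 (-1.24) and ETFA (-0.80) fell, whereas the carnitine palmitoyltransferase CPT1A (0.82) and HADHA (0.46) were among the rises. The adjusted p was 0.00140 with the preset and 0.222 with an estimated correlation. In glycolysis and glucose uptake 10 of 16 genes fell and 2 rose (10 and 2 adjusted over the list alone), with falls in PDHB (-1.90), HK1 (-1.28), the glucose transporter SLC2A1 (-1.18) and ENO1 (-1.05) and rises in PKM (0.28) and PFKP (0.29), and adjusted p = 0.156 with an estimated correlation.

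Most cell cycle, proteasome and heat shock genes also fell in fat. In the cell cycle list 12 of 18 fell (14 adjusted over the list alone), with TOP2A at -2.01, RRM2 at -1.88, CCNB1 at -1.82 and BIRC5 at -0.89, and adjusted p = 0.158 with an estimated correlation. Of 28 proteasome subunits 21 fell (23 adjusted over the list alone) by smaller amounts, such as PSMB7 (-0.64) and PSMD8 (-0.55), with adjusted p = 0.224 with an estimated correlation. Of 14 heat shock genes 8 fell (9 adjusted over the list alone), led by HSPB1 (-1.29), with adjusted p = 0.199 with an estimated correlation. Autophagy and lysosome genes had 7 rises and 2 falls among 19 (7 and 2 adjusted over the list alone), with cathepsin D (CTSD, 0.57), GABARAPL1 (0.59) and SQSTM1 (0.39) higher and ATG7 (-0.57) lower, and adjusted p = 0.183 with an estimated correlation. Among extracellular matrix genes 8 of 21 fell and 3 rose (9 and 3 adjusted over the list alone), with lumican (LUM) at -1.24, COL5A1 at -1.23 and TIMP2 at 0.66.

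Other lists changed in part in fat. Gluconeogenesis split, with PCK1, NR3C1 (0.49) and PC (0.38) higher and GPT (-1.62), GOT1 (-0.90) and SLC37A4 (-0.50) lower, 3 each of 12 and 3 each adjusted over the list alone, with a median of 0.16, a mean of -0.099 and a camera direction of down. Amino acid catabolism had 4 falls, such as BCKDHB (-1.56) and CTH (-1.09), and 2 rises, OAT (0.33) and BCKDHA (0.34), among 14 (4 and 2 adjusted over the list alone). ANGPTL4, an inhibitor of lipoprotein lipase, rose (1.32), 1 of 8 PPARA-responsive genes and 1 adjusted over the list alone. IGF1R (0.52), JAK2 (0.35) and IGF2 (0.30) rose and IGFBP6 (-1.17) and IGF1 fell among 15 growth hormone axis genes (3 and 2 adjusted over the list alone). In the insulin and FOXO list GADD45B (0.90), GADD45A (0.52), CCNG2 (0.31) and AKT1 (0.28) rose and CDKN1A (-0.96) fell, 4 and 1 of 12 (4 and 1 adjusted over the list alone). The clock genes ARNTL (0.70), BHLHE40 (0.63) and RORA (0.43) rose and DBP (-0.59) fell, 3 and 1 of 7 (3 and 2 adjusted over the list alone). Of 17 protein folding genes 5 rose, among them CANX (0.42) and ATF4 (0.30), and 5 adjusted over the list alone.

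Some plasma protein and detoxification genes changed in fat. As 2317 of all 6765 represented genes passed there, the counts below do not set these lists apart. ITIH1 and ORM1 (0.32) were among 4 rises in 17 acute phase genes (4 adjusted over the list alone), although the list's median was -0.094 and its mean -0.067. GSTO1 (-0.83) and EPHX1 (-1.06) were among 4 falls and FMO1 (0.48) with CYP2B22 among 3 rises in 23 xenobiotic genes (4 and 3 adjusted over the list alone). CYP7A1 (-1.90) and AMACR (-0.78) fell, 2 of 7 bile acid genes (2 adjusted over the list alone), and RPL13 (-0.20) fell, 1 of 50 ribosomal protein genes (0 adjusted over the list alone). IFIT1 (0.69) and IFIT2 (0.32) rose, 2 of 13 interferon response genes (2 adjusted over the list alone).

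Some cell type lists also changed in fat. Endothelial markers were higher in fasted fat, 7 of 13 members (8 adjusted over the list alone), with CLDN5 at 1.11, TEK at 0.89, VWF at 0.67 and ESAM at 0.56. The mean of that list was higher by 0.48 in 12 fasted than in 12 fed gilts (adjusted p = 0.000680, 2-sided permutation test, 17 measures), while the camera call (adjusted p = 0.00173) was lost with an estimated correlation (adjusted p = 0.251). Of 14 adipocyte markers LPL and CEBPA (-0.44) fell and CFD, adipsin, rose (0.44), with a list median of -0.026. Fibroblast markers split, with LUM, DPT (-0.81) and THY1 (-0.76) lower and PDGFRB (0.43) and CD34 (0.35) higher, 3 and 2 of 8 (3 and 2 adjusted over the list alone). SPP1 (0.79) rose among 13 macrophage markers (0 adjusted over the list alone), HBB (0.36) among 3 erythroid and APOA1 (0.70) among 14 hepatocyte markers (1 each adjusted over the list alone), CA3 (-1.56) fell among 19 muscle markers (1 adjusted over the list alone), and none passed among 11 lymphocyte and 6 keratinocyte markers. Skeletal muscle markers varied widely between fat arrays, from a list mean of 4.59 to 12.60, but fasted and fed arrays differed by 0.075 in the mean. The hepatocyte markers stood at 9.24 to 9.54 in 4 fat arrays, 1 of them fasted, and at 5.52 to 6.29 in the other 20.

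**Figure D3:**
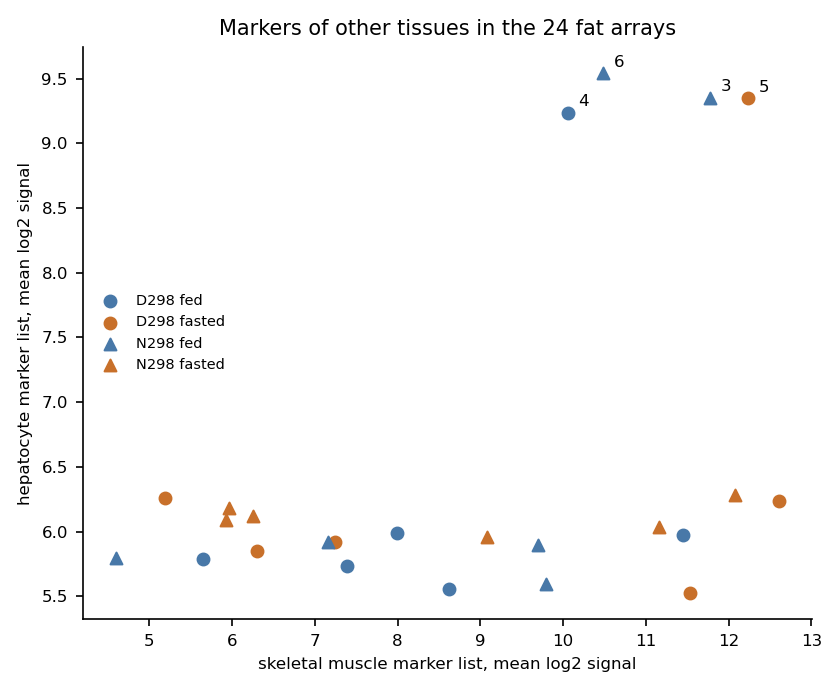
Mean log2 signal of the skeletal muscle marker list (x axis) and of the hepatocyte marker list (y axis) in the 24 fat arrays, 1 point per gilt, by genotype and feeding state. The 4 arrays with a hepatocyte mean of 9.24 to 9.54 carry their replicate number, and muscle means run from 4.59 to 12.60 over all 24 arrays.

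Without the 4 arrays with hepatocyte transcripts 4518 probe sets passed in fat, ACO1, ATF4, BCKDHA, CD34, CEBPA, GADD45A, HMGCS1, IGF1, IGF2, NR3C1, OAT, PFKP, RORA, RPL13, SLC37A4 and SPP1 lost their calls in 1 or more of the fits without certain arrays, and PCK1 lost its call (adjusted p = 0.0797, 0.00105 to 0.0797 over its alternatives). After quantile normalization or median-centring ACO1, AKT1, ATF4, BCKDHA, GADD45A, IFIT2, IGF2, OAT, PFKP, RPL13 and SPP1 lost their calls, and the fall of RPL13 vanished (adjusted p = 0.993 after quantile normalization). With 32 added before log2, which damps dim genes, CYP7A1 moved to -0.75 and RRM2 to -1.07, both still called. ATF4 moved to 0.47 after quantile normalization and RORA to 0.24 without the 4 arrays. The balance of rises and falls depended on scaling, with 2302 higher and 3032 lower (43.2% higher, against 60.1%) after median-centring, under which all 31 oxidative phosphorylation genes were still lower.

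The next question was whether liver and fat respond alike, and it was tested on all 48 arrays as the difference of the fasting responses. They differed for 3864 probe sets, 2121 with a higher response in fat and 1743 with a higher response in liver. CYP2B22 fell in liver (-1.81) and rose in fat, a difference of 3.71 ± 0.41 (SE). The sterol genes SQLE (difference 2.54) and HMGCS1 (2.44) fell further in liver than in fat, where HMGCS1 fell by 0.49 and SQLE gave -0.45 without passing (it passed after quantile normalization or median-centring, and without replicate number 1, and gave -0.27 without the 4 fat arrays with hepatocyte transcripts). ACSL4, an acyl-CoA synthetase, differed by 2.16 and SULT1A3 by 2.11. The 5 largest differences the other way were PGLYRP2 (-3.81), CKB (-3.61), SLC25A1 (-3.33 ± 0.17 SE, adjusted p = 1.58e-19), NNAT (-2.89) and PMM1 (-2.38). Of the 38 genes named for fasting in either tissue 33 differed between the tissues, against 3864 of all 23999 probe sets, but they were named for a large change in 1 tissue, which favours a difference.

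Lists of oxidative metabolism responded lower in fat than in liver. The median of the difference, fat minus liver, was -0.63 for fatty acid oxidation, -0.68 for the tricarboxylic acid cycle and -0.82 for oxidative phosphorylation, with 17 of 24, 17 of 20 and 30 of 31 members past the threshold and lower in fat. These 3 of the 12 lists with a call at the preset correlation held with an estimated one (adjusted p = 0.000928, 0.0183 and 0.0382). When the test was run on differences within gilts, fatty acid oxidation held (adjusted p = 0.0205) and the other 2 did not (adjusted p = 0.0646 each). Cholesterol genes differed the other way, 9 of 13 with a deeper fall in liver (median 0.74), with adjusted p = 0.0565 with an estimated correlation. Autophagy genes had 10 of 19 members with a higher response in fat and 2 with a lower one (adjusted p = 0.0576 with an estimated correlation), and proteasome genes 18 of 28 with a lower one (adjusted p = 0.101).

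**Figure D4:**
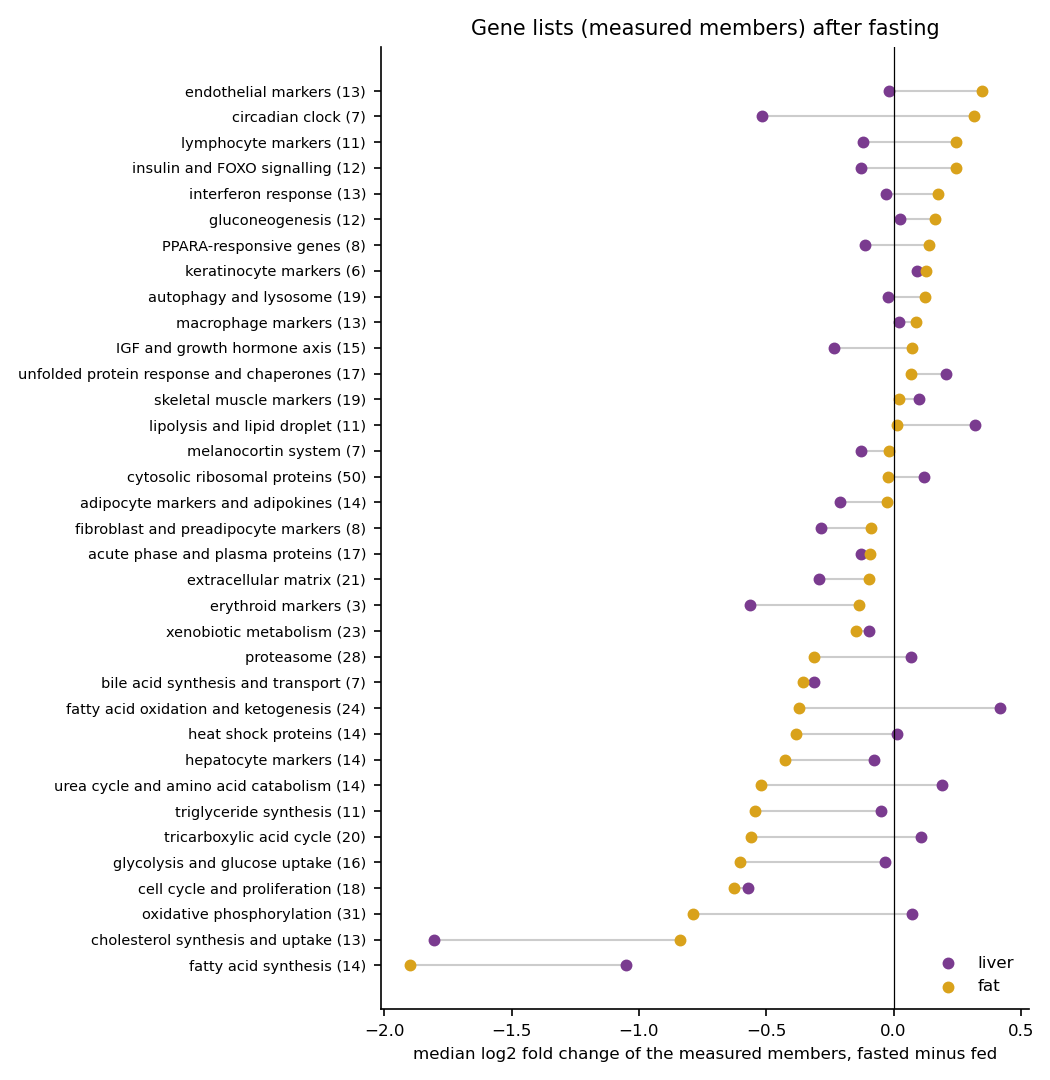
Median log2 fold change after fasting of the measured members of each of the 35 gene lists in liver and fat; the number of measured members stands beside the name. Cholesterol synthesis (-1.81 in liver, -0.84 in fat) and fatty acid synthesis (-1.05 in liver, -1.90 in fat) were lower in both tissues, while oxidative phosphorylation (0.07 in liver, -0.79 in fat) parted.

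Both tissues called 463 probe sets, 287 in the same direction and 176 in opposite directions. Of these, 163 fell in both and 124 rose in both, against 53.1 and 82.5 for independent lists, and 111 rose in liver and fell in fat, against 54.8. Another 65 fell in liver and rose in fat, against 79.9. The counts for independent lists run over all probe sets, dim ones and several per gene included. They do not allow for bright probe sets passing more readily in both tissues, so the excess was not tested. Across probe sets, which are not independent replicates, the log2 fold changes of the tissues correlated with r = 0.085 over all probe sets and r = 0.153 (rho = 0.032) over the 11999 in the upper part of the signal range. When 1 replicate number was left out the same-direction count was 164 to 224 and the opposite count 86 to 119, each lowest without number 3. After median-centring 1000 differences were higher in fat and 2574 in liver (28.0% higher in fat, against 54.9%), and quantile normalization gave 1689 and 2064 (45.0%).

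**Figure D5:**
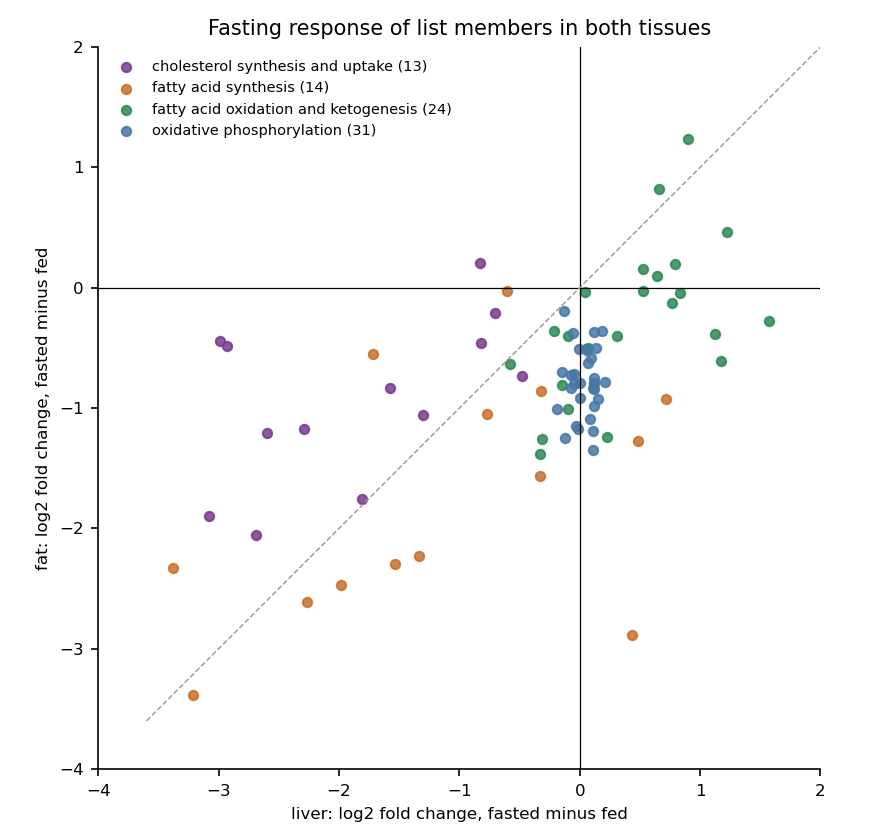
Log2 fold change after fasting in liver (x axis) and fat (y axis) of the members of 4 gene lists, 1 point per gene, with the line of equal response dashed. Oxidative phosphorylation genes lie near 0 in liver and below 0 in fat, with medians of 0.07 and -0.79.

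The series also asked what the N298 form of MC4R changes. No probe set passed for genotype in limma in either tissue, with 1212 at an unadjusted p under 0.05 in liver and 1321 in fat, where chance gives 1200. The smallest adjusted p was 0.0611 in liver and 0.120 in fat. The 0 in liver depended on the replicate block: without it, or with it as a random effect, 1 probe set with no symbol passed (adjusted p = 0.0215 and 0.0200), and without replicate number 3, 2 passed. By the naming rule the 5 genes with the smallest p in liver were IVD, a leucine breakdown enzyme (N298 minus D298 -0.42 ± 0.082 SE, adjusted p = 0.322), FABP5 (0.76), GNE (-0.30), MPDZ (1.23) and SNRPN (0.43). In fat they were SQOR (0.41 ± 0.088 SE, adjusted p = 0.297), POLR1E (0.46), CALML4 (-0.92), CILP (-0.84) and STIP1 (-0.31). None of these 10 passed. The difference in MPDZ rested on replicate number 1, without which it was 0.64. Among the 11999 probe sets in the upper part of the signal range, the 95% confidence interval of the genotype difference lay within 2-fold for 11849 in liver and 11888 in fat. Simulated genotype differences were recovered at 2-fold for 54% of changed probe sets in liver and 50% in fat, and at 1.5-fold for 26% and 38%.

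MC4R itself was near the floor, at a mean log2 signal of 3.17 in liver and 3.64 in fat, and as N298 is a change of the protein, its level does not check the genotype labels. Of 7 melanocortin system genes none passed for genotype in either tissue, and ASIP, the agouti protein that blocks melanocortin receptors, fell on fasting in fat (-0.76). The genotype difference in ASIP was -0.044 in liver and 0.15 in fat. POMC gave 0.70 and 0.20, AGRP 0.32 and 0.049, MRAP 0.33 and -0.17, MRAP2 0.13 and -0.052, MC2R -0.11 and 0.096, and MC4R 0.14 and -0.16. All but MC2R in liver moved by more than 1.5 times among the alternatives. No gene list passed for genotype with an estimated correlation, and 5 in liver and 7 in fat passed with the preset one.

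Whether the genotype alters the response to fasting was tested as the interaction. No probe set passed in liver (smallest adjusted p 0.850, 1390 at an unadjusted p under 0.05) or in fat (0.805, 1368). The 5 smallest p in liver belonged to LOC100519643 (-1.22), LAPTM5 (-0.82), IGFBP1 (1.31 ± 0.33 SE), FGGY (0.92) and THOC5 (-0.58), and in fat to FBLN1 (-1.11 ± 0.23 SE), IFI30 (-1.14), TIMP1 (-0.83), C1R (-1.07) and TAPBP (-0.71). Without the fat of fed D298 replicate number 1, 5 probe sets passed in fat. They were AEBP1 (-2.01), PRELP (-1.40), FBLN1 (-1.27), QSOX1 (-1.03) and a probe set with no symbol. PRELP and FBLN1 encode matrix proteins, and all but FBLN1 were chosen after their values were seen. Simulated interactions were recovered at 2-fold for 20% of changed probe sets in liver and 28% in fat, and at 4-fold for 64% and 76%.

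Fasting was also tested within each genotype. In liver 391 probe sets passed in D298 (182 higher, 209 lower) and 355 in N298 (186 higher, 169 lower), and in fat 3034 (1576 and 1458) and 3718 (2176 and 1542). The fall in FASN was -3.08 in D298 and -3.35 in N298 liver, and -3.34 and -3.42 in fat. PC rose by 1.87 and 1.82 in liver, and CKB gave -3.17 and -3.70 in fat. These counts moved by more than 1.5 times when 1 replicate number was left out: in D298 liver to 232 without number 3 and 248 without 2, in N298 liver to 174 without 3 and 211 without 6, and in D298 fat to 1825 without 3 and 1940 without 5. Without the 4 fat arrays with hepatocyte transcripts, fat gave 1651 in D298 and 2434 in N298. Median-centring changed the share of rises in N298 liver to 80.4% (from 52.4%) and in D298 fat to 31.1% (from 51.9%). Genotype within fed or within fasted gilts gave no probe set in limma (2 in fasted liver without the replicate block or with it as a random effect), with 1225 and 1383 at an unadjusted p under 0.05 in liver and 1085 and 1646 in fat. The smallest p values belonged in fed liver to IVD (-0.50), LAPTM5 (0.52), LCP1 (0.45), PIKFYVE (0.63) and TRIP4 (0.40), and in fasted liver to GNE (-0.55), SGK1 (-0.58), KCNE4 (-1.20), RPS15 (0.35) and LOC100519643 (-0.77). In fat they belonged to C3H2orf40 (-0.99), BCAR3 (-0.49), SQOR (0.44), CHST14 (0.35) and CALML4 (-1.09) in fed gilts, and to FBLN1 (-0.87), FGGY (0.56), SERPINF1 (-0.60), THY1 (-0.74) and STIP1 (-0.48) in fasted gilts.

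Some genes were chosen before the data were examined for their part in fasting. Leptin (LEP), which fat secretes with its fat stores, gave -0.41 ± 0.29 (SE) in fat and adiponectin (ADIPOQ) 0.14, neither past the threshold, and in liver they gave -0.89 and -0.030. Without replicate number 1 the fall in LEP in fat passed, at -0.70, and with 32 added before log2 LEP in liver gave -0.48. PDK4, which holds back pyruvate oxidation, gave -0.11 in liver and 0.24 in fat and did not pass, with a range over the alternatives of -0.22 to -0.043 in liver and 0.060 to 0.38 in fat. CPT1A, the entry enzyme of mitochondrial fatty acid oxidation, rose in liver (0.65, adjusted p = 0.0232) and in fat (0.82). IGF1 gave -0.33 in liver without passing (-0.16 without replicate number 1), and in fat it fell by 0.41, a call lost without replicate number 5. Its other probe sets gave -0.79 and 0.82 in fat. SCD fell by 1.53 in liver and by 2.30 in fat.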

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

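In this part the tests of exchanged samples, feeding state, skeletal muscle, array scaling, adipocyte share and feed intake were chosen only after the result was seen. For the tests of liver RNA and of a mixture the cut-offs were set before the tests were run, but the arrays were picked after the data were seen. Tests of other splits of the arrays were set beforehand.

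Single arrays stood far from the other 5 of their group in 73 of 1020 gene groups, by a gap to the nearest that took up most of the group's range (Dixon's ratio at the 95% level), where chance gives 1 in 20, or 51. Among fasted D298 fat samples these were, with replicate number and ratio, AQP3 (5, 0.631), CCNB1 (1, 0.953), DGAT1 (1, 0.725), FGGY (2, 0.674), HMGCS1 (1, 0.767), HSPB1 (3, 0.655), IGFBP6 (5, 0.662), MC4R (6, 0.796), MDH1 (5, 0.705), OAT (2, 0.654), SLC2A1 (5, 0.661) and SQSTM1 (5, 0.676). Among fed D298 fat samples these were ACACA (1, 0.759), ACSS2 (1, 0.690), BCKDHB (1, 0.640), ENO1 (1, 0.683), FASN (1, 0.639), FDPS (1, 0.634), FMO1 (1, 0.628), GADD45B (5, 0.646), HK1 (1, 0.751), IFIT1 (6, 0.668), LPL (1, 0.710), PGD (1, 0.797), SLC25A1 (1, 0.668) and SLC2A5 (1, 0.766). Among fasted N298 fat samples these were ACSS2 (4, 0.646), DPP4 (4, 0.628), ETFA (2, 0.864), HMGCS1 (3, 0.709), IGF1R (4, 0.662), ITIH1 (2, 0.835), NR3C1 (1, 0.834), PCK1 (3, 0.630), PGD (6, 0.819) and PLLP (4, 0.659). Among fed N298 fat samples these were AKT1 (2, 0.663), CEBPA (3, 0.659), ECI1 (1, 0.727), IGF1 (6, 0.692), IGF1R (3, 0.667) and RRM2 (5, 0.673). Among fasted D298 livers these were HADHA (4, 0.678), IDH1 (3, 0.671), LDHA (2, 0.702), ME1 (6, 0.632), MPDZ (1, 0.702), NEB (2, 0.652) and THOC5 (2, 0.626). Among fed D298 livers these were ABCB1 (4, 0.643), BHLHE40 (5, 0.692), FH (6, 0.756), LAPTM5 (6, 0.684), MPDZ (1, 0.704) and MRAP (5, 0.909). Among fasted N298 livers these were ACSS2 (1, 0.700), APOA4 (1, 0.706), ECH1 (1, 0.681), EPHX1 (1, 0.629), FABP1 (2, 0.664), FABP4 (1, 0.720), MRAP2 (1, 0.681) and SUCLG1 (3, 0.630). Among fed N298 livers these were CYP2C36 (6, 0.642), DEFB1 (6, 0.665), ELOVL6 (5, 0.722), FABP5 (1, 0.720), FH (1, 0.682), GPI (5, 0.680), PC (5, 0.693), PCK2 (2, 0.652), PLIN2 (6, 0.707) and SCD (5, 0.640). The fasted D298 fat of replicate number 1 had a log2 CCNB1 signal of 2.09 against 5.96 to 6.15 in the others.

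Among list means and control ratios 11 of 72 groups had such an array, where chance gives 3.6. They were the actin 3'/5' ratio of D298 fed replicate number 4 in fat (0.823) and liver (0.700), hepatocyte markers in fat of D298 fed 4 (0.882) and fasted 5 (0.807), the interferon response in liver of D298 fed 6 (0.799) and N298 fasted 1 (0.633), and acute phase genes in fat of D298 fed 4 (0.731) and N298 fasted 4 (0.636). Macrophage markers in fat of N298 fed 1 (0.821) and in liver of D298 fasted 5 (0.642) and erythroid markers in liver of N298 fasted 2 (0.659) completed them.

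Liver and fat differed in the fasting response by a test of the difference itself for 3864 probe sets and, with the preset correlation, for 12 gene lists. Of these lists 3 held with an estimated correlation, and 1 of those, fatty acid oxidation, on differences within gilts (adjusted p = 0.0205, against 0.0646 for the other 2). By the same test CYP2B22 (3.71), SQLE (2.54), HMGCS1 (2.44), ACSL4 (2.16) and SULT1A3 (2.11) responded higher in fat, and PGLYRP2 (-3.81), CKB (-3.61), SLC25A1 (-3.33), NNAT (-2.89) and PMM1 (-2.38) lower, on the log2 scale. Fatty acid oxidation (-0.63), the tricarboxylic acid cycle (-0.68) and oxidative phosphorylation (-0.82) had lower medians in fat. For the count of 3864 probe sets 1 of 100 splits of the gilts, the real one, gave as many, and the highest other gave 295. This argues against chance for the count, not for single probe sets. For the 12 lists chance cannot be excluded, as 16 of 100 splits gave as many and the highest other gave 15. For the 287 probe sets called in both tissues with the same sign and the 176 with opposite sign 1 of 100 splits each gave as many and the highest other gave 0 each, but splits call too few probe sets in liver for any to be shared, so the sharing itself was not tested.

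The first pattern is hepatocyte transcripts in 4 fat arrays, D298 fed 4, D298 fasted 5, N298 fed 3 and N298 fed 6, with list means of 9.24 to 9.54 against 5.52 to 6.29 in the other 20 and 14.4 to 14.9 in liver. An exchange of samples is argued against by the adipocyte list mean, at most -0.34 from the median of the other fat arrays. Feeding state stays open, as 3 fed and 1 fasted array are too few to tell (exact test, p = 0.590). A candidate source is liver RNA or tissue at about 0.421% to 0.534% of the liver signal: of 109 other liver-abundant genes 83.5% to 90.8% lay above the median of the other fat arrays (33.0% to 64.2% in those), and the excess followed the liver signal (rho 0.643 to 0.720). The lowest share, 83.5%, missed the 90% set beforehand and stayed above the 60% that would have excluded this source, so it stays open. No biological explanation beyond feeding state was tested.

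The second pattern is the fat of D298 fed replicate number 1, which lay between fed and fasted arrays, with an index of 0.54 on the fasting response (other fed fat -0.19 to 0.24, fasted fat 0.85 to 1.04). That index argues against an exchange with a fasted sample. Lower feed intake acting on both tissues is argued against by the liver of the same gilt, at 0.049 within the other fed livers (-0.16 to 0.22). A mixture with RNA of a fasted sample stays open, since the index over rises exceeded that over falls by 0.17, under the 0.2 set beforehand and within the range of other fed fat (-0.38 to 0.27). A cause in fat alone of this gilt was not tested.

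The third pattern is the fall of all 31 oxidative phosphorylation genes in fasted fat (median -0.79, members from -1.35 to -0.19). Skeletal muscle in the samples is argued against, as among the 6 fed and 6 fasted arrays with the least muscle signal the list mean still differed by -0.83 (95% interval -1.03 to -0.63), against -0.79 over all. In these the fed arrays held more muscle signal than the fasted ones (6.90 against 6.15), and at equal muscle signal the difference was -0.88 (95% interval -1.06 to -0.70) in them and -0.79 (-0.97 to -0.61) over all. For the scalings tried, array scaling is argued against, as 30 were called lower after quantile normalization (median -0.68) and 31 after median-centring (-0.87). Both set arrays to a common level, so a change in the amount of mRNA was not tested. Spiked-in controls added to the RNA were 0.32 higher in fasted fat without passing (permutation test, adjusted p = 0.0636). The GAPDH 3'/5' ratio was 0.41 higher without passing (permutation test, adjusted p = 0.296), and no RNA quality ratio was fitted in fat. A lower share of adipocytes would raise the markers of all other cell types alike if those kept their proportions and their expression. The endothelial list mean rose by 0.48 (permutation test, adjusted p = 0.000680), while the fibroblast list mean changed by -0.28 without passing (adjusted p = 0.0603). The lists moved apart (difference 0.76, with a lower 95% bound of 0.52). Macrophage (0.15), lymphocyte (0.14), keratinocyte (0.30) and muscle (0.075) list means were higher, and erythroid (-0.26) and hepatocyte (-0.38) means lower, none past the threshold. As fasting may also change markers within a cell type, these lists cannot decide the share of adipocytes, which stays open. The adipocyte list mean changed by -0.084 (95% interval -0.20 to 0.036). A change in endothelial cells stays open. A response of fat to fasting may underlie it, as a hypothesis found and tested on the same arrays.

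Splits that exchange feeding labels within replicate number were counted for each fasting result. For the counts of 1073 probe sets in liver and 6048 in fat, 1 of 100 splits each, the real one, gave as many (highest other 17 and 131). This argues against chance for the counts, not for single probe sets. Within genotype the real split ranked first of 32 in liver, for D298 (391, highest other 64) and N298 (355, highest other 1). It also ranked first of 32 in fat, for D298 (3034, highest other 2442) and N298 (3718, highest other 304). As 1 of 32 is the smallest share these splits can give, with no adjustment for several tests, chance is not firmly excluded within genotype. The split with 2442 exchanged replicate number 1 alone, the number of the intermediate array, and so did the one with 304. For the number of gene lists called at the preset correlation chance cannot be excluded in fat (12, 24 of 100 splits, highest other 19). In liver 3 of 100 splits gave as many as the real 15, under the share set beforehand. Another split there called 16, more than the real labels, so chance is not firmly excluded. Nor does the count secure single lists: the median of the other splits in liver was 7, and with an estimated correlation 1 list held in liver and 0 in fat.

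Exchanging genotype labels could not test the real counts of 0 probe sets, since every split gives at least as many. For genotype this was 100 of 100 in liver and fat (highest other 1 each), for the interaction 100 of 100 (highest other 1 in liver, 2 in fat), and within fed or fasted gilts 32 of 32 (highest other 1 and 0 in liver, 1 and 2 in fat). For the 5 lists under genotype in liver (70 of 100, highest other 13) and the 7 in fat (47 of 100, highest other 16) chance cannot be excluded.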

How the results depend on the processing

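The fits without certain arrays or gilts, with covariates, the genotype contrast over both tissues and the estimated correlation for list differences were chosen after seeing the data. Of 4822 alternatives over 270 gene results, 4557 kept direction and side of the threshold, 211 lost the call, 12 gained one and 42, from 14 results, changed sign without passing the threshold on either side. ADIPOQ for fasting in liver gave -0.030, and 0.083 after quantile normalization, 0.027 after median-centring, 0.022 with array weights, 0.013 without liver D298 fasted 2 and -0.13 to 0.097 without 1 number. AGRP for genotype in fat gave 0.049, and -0.032 with array weights, -0.25 without D298 fed 4, -0.12 without fat D298 fed 1, -0.17 without the 4 fat arrays and -0.28 to 0.28 without 1 number. AGRP for genotype in liver gave 0.32, and -0.12 to 0.73 without 1 number. ASIP for genotype in fat gave 0.15, and -0.027 without the 4 fat arrays. ASIP for genotype in liver gave -0.044, and 0.014 without D298 fed 4 and -0.13 to 0.066 without 1 number. MC2R for genotype in fat gave 0.096, and -0.0078 to 0.25 without 1 number. MC4R for fasting in fat gave -0.15, and -0.42 to 0.045 without 1 number. MC4R for fasting in liver gave -0.13, and 0.059 after quantile normalization, 0.39 with the RNA ratio and -0.47 to 0.19 without 1 number. MC4R for genotype in fat gave -0.16, and 0.011 with 32 added before log2 and -0.87 to 0.33 without 1 number. MC4R for genotype in liver gave 0.14, and -0.54 to 0.55 without 1 number. MRAP for genotype in liver gave 0.33, and -0.057 to 0.90 without 1 number. MRAP2 for genotype in fat gave -0.052, and 0.096 with array weights, 0.24 without fat D298 fed 1, 0.15 without the 4 fat arrays and -0.45 to 0.15 without 1 number. MRAP2 for genotype in liver gave 0.13, and -0.065 to 0.38 without 1 number. PCK1 for fasting in liver gave -0.038, and 0.020 after median-centring, 0.011 with the RNA ratio and -0.13 to 0.018 without 1 number.

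Without replicate block, or with it as a random effect, 1 probe set passed for genotype in liver (with no symbol) and 2 within fasted liver (the same and GNE, -0.55). Without trend ABHD5, ARG1, CPT1A, DEFB1, FABP1, FABP4, FH, GABARAPL1, IGFALS, IGFBP2, ITIH3, PCK2, PSMC2, SDHD, SPARC, SUCLG1 and VNN1 in liver and SPP1 in fat lost their calls, and ARG1, FABP1, GABARAPL1 and IGF2 in liver without block or with a random one. With the RNA ratio, the elongation factor 3'/5' ratio as a covariate, FABP1, FABP4, GABARAPL1, IGFBP2, ITIH3, MCM2, PCK2, PSMC2, SPARC and VNN1 lost theirs in liver. With array weights ARG1 and PSMC2 lost theirs in liver, and with muscle and hepatocyte list means as covariates SPP1 in fat. eBayes without trend gave 240 in D298 liver, 223 in N298 liver and 97 shared with opposite sign. Without the fat arrays with liver transcripts 1651 passed in D298 and 2434 in N298 fat.

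Leaving out 1 replicate number or array, counts ranged from 667 to 1037 for fasting in liver, 232 to 346 in D298 and 174 to 397 in N298 liver, and in fat from 4761 to 6270, 1825 to 3641 in D298 and 2649 to 3804 in N298. Genotype gave 0 to 2 in liver (without number 3, with CTSC at 0.72) and 0 to 1 in fat (with no symbol, without D298 fed 4), within fasted fat 0 to 2 (with no symbol, without number 1), within fed fat and within fed or fasted liver 0 to 0. The interaction gave 0 to 0 in liver and 0 to 5 in fat, with 4 without number 1 (AEBP1, PRELP, QSOX1 and C1R). Shared calls ranged from 164 to 224 with the same sign and from 86 to 119 with opposite sign, and the tissue difference from 2764 to 3658. These fits have fewer samples. The cause of the other changes was not tested.

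No list past the threshold at the preset correlation changed direction after quantile normalization or median-centring. With an estimated correlation 1 list held for fasting in liver, 0 in fat, 0 for genotype in each tissue and 3 for the tissue difference. fry gave 20 lists for fasting in fat and 0 for genotype in each tissue. With the muscle list mean as a covariate and an estimated correlation 1 list held for fasting and 0 for genotype in fat.

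Replicate numbers paired arrays within a tissue weakly at most. Arrays of the same number had residual r of -0.23 to 0.21 in liver (median 0.061, against -0.0096 for other pairs). In fat it was -0.35 to 0.50 (median 0.062, against -0.037 for other pairs). Of the 24 arrays of a tissue, 5 in liver and 8 in fat correlated best with their own number. Signal near the floor limits MC4R and other dim genes, as the lowest signal was 0.0672.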

Other observations

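The genotype contrast over both tissues, the test of genes neighbouring MC4R and the relations between list means were chosen only after the data were seen.

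Over both tissues together 9 probe sets differed by genotype, 8 of them higher in N298, with 1225 at an unadjusted p under 0.05. GNB5, a G protein subunit on the chromosome of MC4R, was higher in N298 by 0.66 ± 0.12 (SE, 24 gilts, adjusted p = 0.00759), and SEPT7, a septin, by 1.10 ± 0.23 (SE, adjusted p = 0.0426). The smallest p belonged to a probe set with no symbol (1.08 ± 0.14 SE, adjusted p = 6.99e-06, 1.08 in each tissue). The model used 1 within-gilt correlation, 0.084, for all probe sets. Where the liver and fat of a gilt are more alike in a probe set, its error and p value here are too small. Of 100 splits of the gilts only 1, the real one, gave as many as 9, and the highest other gave 4. The splits argue against chance for this contrast, but do not allow for its choice after the data were seen. Of genotype differences over both tissues simulated with the correlation of 0.084, 76% were recovered at 2-fold.

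A hypothesis is that gilts with N298 share a stretch of chromosome around MC4R, so that neighbouring genes differ with it. Of the 50 measured genes nearest to MC4R in the RefSeq assembly 9 had a p under 0.05 over both tissues, against a median of 2 in windows of 50 genes elsewhere. Of 5609 windows 5 had as many. Neighbouring windows overlap, so these 5 may share the same stretch, and 5 of 5609 does not measure how rare 9 is. The 9 genes were CALML4 (-0.73), SMAD3 (-0.58), SERPINB2 (-0.61), ZNF236 (0.40), TIPIN (0.38), CNDP2 (-0.26), TMX3 (0.20), HACD3 (-0.19) and MTMR10 (0.14), each with the same sign in both tissues, chosen after their values were seen and none past the adjusted threshold. Among splits of the gilts 2 of 100 gave as many, and the others had a median of 3 and a highest count of 9. As this test was chosen after the data were seen, chance is not excluded. A linked region may contribute to differences between these genotype groups that are not effects of MC4R itself, and the 9 genes do not tell the causes apart.

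The interferon response list varied between gilts in both tissues. Deviations from group means correlated between the liver and fat of 24 gilts with r = 0.760 (adjusted p = 0.00036, 2-sided permutation test, 6 relations) and rho = 0.557 (adjusted p = 0.0112), and with r = 0.674 without the 2 farthest gilts. The list mean was high in D298 fasted 5 (11.1 in liver, 9.79 in fat) and fed 6 (10.9 and 9.89), and D298 fasted 2 had the highest value in fat, 10.1. In liver its SD was 0.82 over 12 D298 and 0.20 over 12 N298 gilts. The permutation test does not allow for this unequal spread, so the relation may rest on a few D298 gilts. Macrophage markers gave r = 0.415 (adjusted p = 0.0664), acute phase genes -0.243 (adjusted p = 0.307) and protein folding genes 0.019 (adjusted p = 0.917) in the same comparison.

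In fat the muscle list mean fell with a higher GAPDH 3'/5' ratio (24 arrays, r = -0.658, adjusted p = 0.00198, rho = -0.650, and r = -0.683 without the 2 farthest). In liver the acute phase list mean rose with the elongation factor 3'/5' ratio (r = 0.493, adjusted p = 0.0291, rho = 0.562, and r = 0.678 without the 2 farthest). Both relations pooled the 24 arrays of a tissue without centring on group means. In fasted liver the acute phase mean (-0.18) and this ratio (-0.062) were both lower, neither past the adjusted threshold. Feeding state may thus contribute to the relation in liver.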
